A study of Mus musculus with 10 samples.

How the data were processed

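Mature CD4 single-positive (CD4SP) and CD8 single-positive (CD8SP) thymocytes were compared. These are the T cells that have completed selection in the thymus and have committed to the helper or to the cytotoxic lineage. Per the labels, cells came from C57BL/6 mice, thymi were pooled for each sample, beads removed cells carrying the other coreceptor, double-positive thymocytes included, and a flow sorter then kept TCRβ-positive, CD24-negative cells of each lineage. The 10 samples comprised 1 long-read library per lineage and 4 short-read samples per lineage, and the short-read labels differ only by sequencing lane. The short-read values of each lineage are given in 1 file that pools the lanes, so each lineage has a single value per gene and no replicate.

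Long-read libraries were made from total RNA by full-length cDNA amplification and each was sequenced on its own PacBio cell, per the labels' protocols. Each deposited long-read table lists collapsed isoforms with their length, exon number, structural category and the percent of A in the genomic window after the 3' end, per the file headers. The columns for full-length read counts and junction coverage are empty, so the depth behind an isoform is unknown and isoforms were counted once each. Short-read libraries were paired-end and depleted of ribosomal RNA, per the labels' protocols. The deposited short-read files hold FPKM (fragments scaled to transcript length and library size) with an interval for each RefSeq or assembled transcript, written by Cufflinks per the file headers. A further deposited table gives TPM (transcript abundance scaled to a common total) over a catalogue chained from both long-read libraries, and although its headers say counts, both columns have the same total, as TPM has. The reads behind these TPM values are not given in the sources used here, and they were taken as short reads because some isoforms of the catalogue are at 0 in both columns. Its identifiers are not paired with gene names and were not matched to the isoforms of the separate libraries. The submitters' processing notes name GRCm38, GSNAP, FastQC, Trimmomatic, RSEM 1.3.1, TopHat2 2.0.14 and Cufflinks 2.1.1, without the role of each. The number of reads per library is not given in the sources used here.

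Transcripts were assigned to genes through RefSeq identifiers of the GRCm38.p6 gene table, of which 30018 of 30604 matched a symbol, and assembled spliced transcripts were added to a gene where they shared an intron with it and with no other gene. Those that shared introns with several genes were left out of gene FPKM but entered the splicing events. Gene positions come from GENCODE release M21 on GRCm38. Exon numbers count within a single GENCODE transcript that holds the exon and are not a numbering of the whole gene. Gene FPKM is the sum over the transcripts of a gene, and its interval is the sum of the deposited intervals. In 4.89% of RefSeq transcripts of CD4SP and 5.19% of CD8SP the deposited FPKM lies outside its own interval. Over all listed transcripts, most of them single-exon fragments, these shares are 35.8% and 37.1%. Some gene sums lie outside their summed intervals too, among them Zbtb7b, Tnfrsf4, Socs3, Foxp3 and Ly6a in CD4SP and Itgae, Runx3, Cst7 and Cd28 in CD8SP. The intervals are thus an incomplete measure of error. A gene was called when its higher FPKM was at least 1, the log2 ratio with a pseudocount of 0.1 was at least 1 in size, and the intervals did not overlap. Log2 ratios are on the log2(FPKM + 0.1) scale, which understates the change of low genes. Each called gene was also compared in an exon-based value, in which every transcript of at least 200 bases counts by the share of the gene's RefSeq exons it covers. It rests on the same deposited FPKM and is not an independent check. Genes of multigene families, such as histones and the Klra receptors, can share reads and are uncertain. An FPKM of exactly 0 can be a failed estimate, since genes that all cells use are among those at 0.

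Splicing events of 7 types were built from the intron chains of both files, and the percent spliced in (PSI) is the share of summed FPKM carried by isoforms with the longer or upstream form. An event was tested at a summed FPKM of at least 1 in both libraries and called when PSI differed by at least 20 percentage points. A retained intron needed an exon reaching at least 10 bases beyond the intron on each side. PSI ranges came from 400 draws from the deposited FPKM intervals. Isoform usage in the chained table was called where the share of an isoform within its locus differed by at least 20 points at a locus total of at least 1 TPM. Shares of long-read isoforms were compared with 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the items of each family, and intervals are exact Clopper-Pearson at the 95% level. These tests and intervals cover counting error between the libraries only and say nothing about differences between mice. Isoforms were called A-rich where at least 60% of the bases after the 3' end were A.

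The median log2 ratio of each of 13 gene lists was placed among 10000 random lists of the same size, matched in 20 bins of expression, where at least 3 members reached 1 FPKM. The lists were the CD4 and CD8 lineages, regulatory T cells, mature and immature thymocytes, innate-like T and NK cells, B cells, myeloid cells, stroma, erythroid cells, proliferation, splicing regulators and genes with known T cell splicing, and some genes are in more than 1 list. The lists, the thresholds and the rules for naming genes were fixed before the data were examined. Named were Cd4, Cd8a and Cd8b1, the members of the lineage lists, the 4 largest log2 ratios among called members of each other list, the 12 largest ratios per direction among protein-coding genes at 5 FPKM or more, the 4 largest events of each type at 5 FPKM or more, called events of genes with known T cell splicing, and the 5 genes with the most isoforms per library. Predicted genes and receptor segments were left out of the largest ratios. List members that did not pass, uncalled events and the isoform numbers of lineage genes were named after their values were seen. Some genes these rules take are not reported here. Further genes and events, restricted to values above 0 in both libraries or to forms annotated in RefSeq, were named by rules chosen after the data were seen, and the text says so. The design had foreseen isoform tests on full-length reads and matching of intron chains between long-read libraries. Without read counts or exon positions, the TPM rule foreseen for that case was used for isoform usage, and isoforms were called shared where both libraries held a multi-exon full match to the same reference transcript. That definition, and the use of isoform numbers per gene in place of reads for the comparison of long and short reads, were chosen after the files were seen.

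The searches were tested on simulated data. The event search recovered all 2800 simulated events. Among 23005 genes, the gene rule called 97.8% of genes changed 2.5-fold and 100% of those changed 4-fold or 8-fold. It called 0 of 49 changed 1.5-fold and 22 of 22805 unchanged genes. The noise of these simulated genes came only from the widths of the deposited intervals, without failed estimates at 0 or library effects. In the real data only 9620 of the 23005 genes reach 1 FPKM in either library, and the rest cannot be called. The rate among unchanged genes is thus too low to stand for the real calls. The category test recovered 395 of 400 shifts of 3 points and called 7 of 1000 unchanged categories, and the usage rule found 200 of 200 loci shifted by 40 points and 0 of 1121 others. Of 100 random lists, 5 fell outside the middle 95%, and all 20 lists shifted by 0.8 did. Alternatives covered the pseudocount, expression minimums, thresholds, scaling, interval rules, minor isoforms, single-exon and A-rich isoforms and list matching. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.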

Results

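Helper and cytotoxic T cells arise from the same precursors in the thymus, and the study asked how far the 2 lineages differ in the splicing of their transcripts. The long-read tables held 8289 isoforms for CD4SP and 9476 for CD8SP cells, assigned to 3031 and 3602 annotated genes. The short-read files listed 686660 transcripts for CD4SP and 637618 for CD8SP, most of them single-exon fragments. With a single pooled value per lineage there is no replicate check of any difference, so genes are called by size and by separate deposited intervals, events by size alone, and no p-value is given for them.

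The coreceptor genes followed the labels. Cd4, the coreceptor of helper cells (chromosome 6, 124864692 to 124888221, GRCm38), stood at 107 FPKM in CD4SP and 1.69 in CD8SP, a 63.4-fold difference. Cd8a (chromosome 6, 71373427 to 71379173) was 22.1-fold higher in CD8SP, at 241 against 10.9 FPKM, and Cd8b1 (chromosome 6, 71322788 to 71337494) was 15.3-fold higher, at 505 against 32.9 FPKM. In long reads, Cd4 had 3 isoforms in CD4SP, among them a full match of 10 exons and 3082 bases, and 0 in CD8SP. Cd8b1 had 0 isoforms in CD4SP and 2 in CD8SP, including a full match of 6 exons and 1450 bases. No isoform of Cd8a was listed in either long-read library.

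Genes of the helper program were higher in CD4SP cells. Of 14 CD4 lineage genes measured, 7 were higher in CD4SP and 1, the cytokine signalling inhibitor Socs3, in CD8SP (2.42 against 5.37 FPKM), a call lost after scaling. Zbtb7b, which encodes the transcription factor ThPOK that directs helper commitment, reached 22.5 FPKM in CD4SP and 0.0606 in CD8SP, although the former lies outside its own deposited interval of 28.5 to 33.7. Cd40lg, the ligand with which helper cells activate B cells, was 31.1-fold higher in CD4SP, Itm2a 9.19-fold, Gata3 3.82-fold and Cd28 3.50-fold. Tnfrsf4 stood at 12.6 FPKM in CD4SP and was listed at 0 in CD8SP. Outside their intervals too were Tnfrsf4 in CD4SP (13.1 to 16.1), Socs3 in CD4SP (2.47 to 3.08) and Cd28 in CD8SP (15.4 to 16.6). Tox, Icos, Cd5, Cd6, St8sia1 and Bcl6 did not pass, with ratios between -0.87 and 0.12 on the log2 scale, and St8sia1 passed in CD4SP after scaling. The list's median log2 ratio of CD8SP to CD4SP was -1.33, at percentile 0 of matched random lists.

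Genes of the cytotoxic program were higher in CD8SP cells. Of 18 CD8 lineage genes measured, 13 were higher in CD8SP and 3 in CD4SP, and the median log2 ratio was 2.54, at percentile 100. Itgae, the integrin chain CD103, was 60.3-fold higher at 46.0 FPKM, the granule protein gene Nkg7 was 13.8-fold higher at 169.6 FPKM, and Cst7, Klrd1, Eomes and Xcl1 were between 8.27-fold and 11.2-fold higher. Runx3, the transcription factor of the cytotoxic lineage, differed less, at 9.23 FPKM in CD8SP and 3.15 in CD4SP. The CD8SP FPKM of Itgae lies below its deposited interval of 53.2 to 57.6, and that of Runx3 below 11.7 to 13.2. Cst7 in CD8SP lies above its interval of 24.1 to 27.2. Ctsw, Dapl1, Crtam and Il2rb were also higher in CD8SP. The death ligand gene Fasl (1.5 against 0.111 FPKM), the chemokine receptor gene Cxcr3 (3.03 against 1.14) and Klre1 (2.65 against 0.208) were higher in CD4SP. Ccr9 and Ly6c2 did not pass, at log2 ratios of 0.65 and 0.85, and Gzmm stayed under 1 FPKM.

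**Figure D1:**
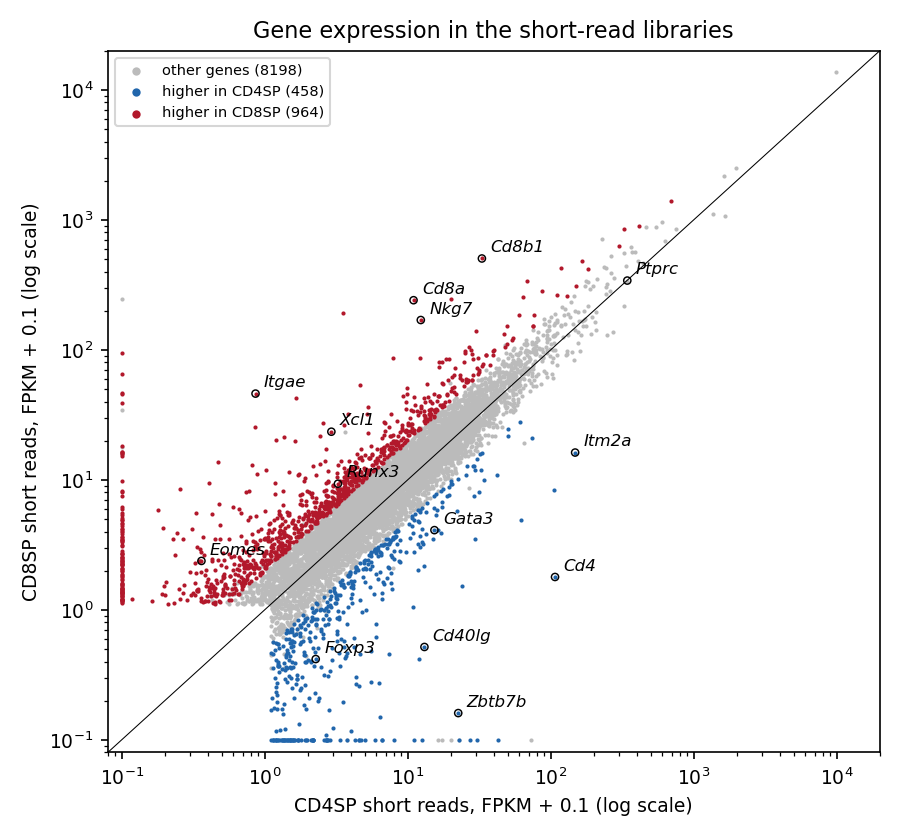
Gene FPKM plus 0.1 in CD8SP against CD4SP short reads on log axes, 1 point per gene at 1 FPKM or more in either library, with 964 genes called higher in CD8SP in red, 458 higher in CD4SP in blue and the line of equality. Cd4, Zbtb7b and Cd40lg lie far to the CD4SP side, Cd8a, Cd8b1, Nkg7 and Itgae to the CD8SP side, and Ptprc lies on the line.

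Cell cycle genes were higher in CD8SP cells. Of 14 proliferation genes, 12 were called, all in that direction, with a median log2 ratio of 1.36 at percentile 100. The replication licensing gene Mcm3 was 3.41-fold higher at 28.4 FPKM, Rrm2 3.16-fold, Aurkb 3.16-fold and Birc5 2.80-fold. Mki67 and Ccnb1 did not pass, at log2 ratios of 0.96 and 0.59. After scaling of the libraries to a median log2 ratio of 0, 11 of the 14 were called and the median was 1.15.

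Several smaller groups leaned to CD4SP. Of 11 regulatory T cell genes measured, 3 were higher in CD4SP and 0 in CD8SP, with a median of -0.37 at percentile 0.46: the lineage factor Foxp3 (2.18 against 0.318 FPKM), Il2ra (3.22 against 0.366) and Nrp1 (3.12 against 0.589). Of 10 immature thymocyte genes, the recombinase gene Rag1 (12.5 against 4.12 FPKM) and Arpp21 (5.54 against 2.07, and 1.05 against 0.505 in the exon-based value) were higher in CD4SP, and the median was -0.27 at percentile 0.98. Of 4 innate-like T and NK genes measured, Klrb1c (3.26 against 0.268 FPKM) and Il17rb (3.66 against 0.365) were higher in CD4SP, with a median of -1.68 at percentile 0.49. Genes of mature thymocytes and their egress had a median of 0.29 at percentile 41.3, with Itgb7 (28.3 against 85.2 FPKM) and Gimap5 (4.38 against 9.06) higher in CD8SP, the latter only before scaling, and Ly6a (12.03 against 2.93) higher in CD4SP.

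Few markers of other cell types reached 1 FPKM. Of 13 myeloid and dendritic genes 3 were measured, of which H2-Ab1 was higher in CD4SP at 1.32 against 0.254 FPKM, and the median was -0.67 at percentile 4.19, or 2.44 among random lists not matched on expression, outside their middle 95%. Of 10 B cell genes 8 were matched, and Cd79b, the only one at 1 FPKM or more, was higher in CD8SP at 5.49 against 0.583 FPKM. Its partner Cd79a was listed at 0 in both but had the opposite direction in the exon-based value, at 7.05 in CD4SP and 0.248 in CD8SP. Of 2 erythroid genes, the globin gene Hba-a2 was higher in CD4SP at 2.01 against 0.304 FPKM, and of 2 stromal genes, Epcam and Pecam1, 0 were called.

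**Figure D2:**
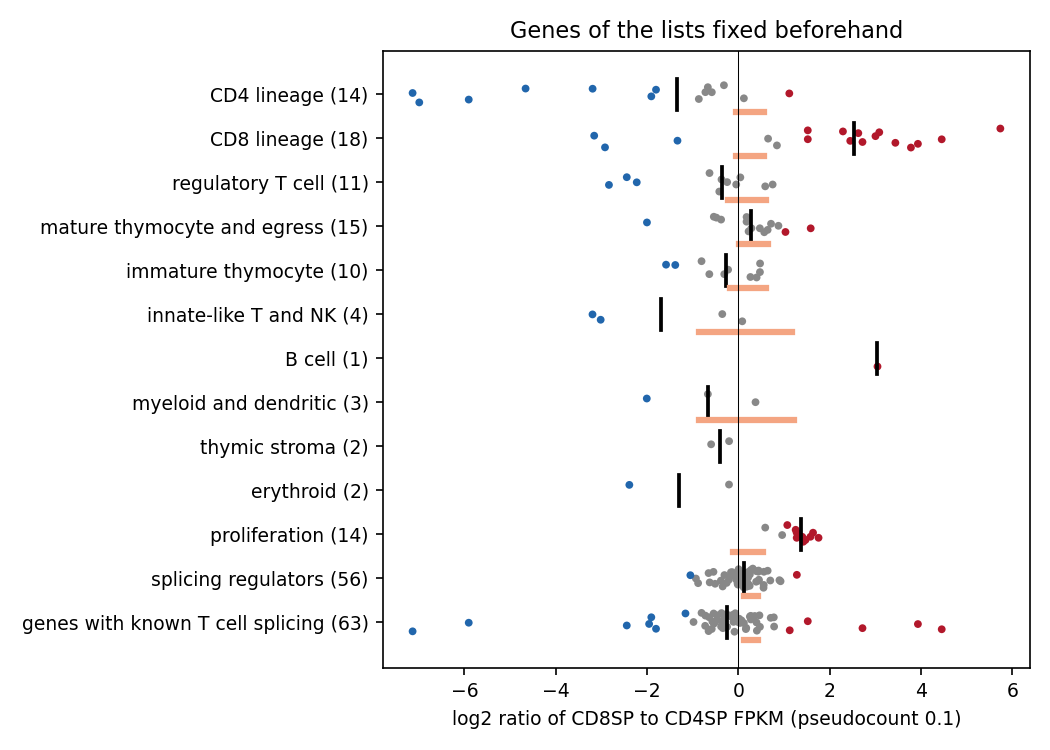
Log2 ratio of CD8SP to CD4SP FPKM for each measured gene of the 13 lists, with the number measured in parentheses, called genes in blue (higher in CD4SP) or red (higher in CD8SP), medians as black bars and the middle 95% of medians of matched random lists as orange bars where at least 3 genes were measured. The CD8 lineage median of 2.54 and the proliferation median of 1.36 lie right of that range, and the CD4 lineage median of -1.33 lies left of it.

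Over all 9620 genes at 1 FPKM or more in either library, 1422 were called, 964 higher in CD8SP and 458 higher in CD4SP. The median log2 ratio of genes at that level in both libraries was 0.21, and after scaling it to 0 the split was 656 to 637, with 1114 calls shared. Across 8699 genes in both, log2 FPKM correlated at a Pearson coefficient of 0.916, a description across genes, which are not independent replicates. In the exon-based value 93.5% of called genes kept their sign and 56.5% still differed by at least 2-fold.

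Among protein-coding genes at 5 FPKM or more, most of the largest ratios came from genes listed at 0 in a library. This held for 20 of the 24 genes taken by the fixed rule. Higher in CD4SP were Gpbp1 (30.2 FPKM), Polg2, Sox4, Zbtb7b, Tnfrsf4, Senp3, Rnf146, H2bc7, Clec2h, Cd4, the Klra receptor gene Klra9 and the adhesion gene Chl1. Among those higher in CD8SP were Cct2 (94.6 FPKM), Brd2 (46.4 FPKM), S100a11, the potassium channel gene Kcna3, Lars, Cbx3, Ppil3, Qprt, Dapk3, Ms4a4c and Eif4e3, all listed at 0 in CD4SP. Of the 24, 21 also differed by at least 2-fold in the same direction in the exon-based value. That value rests on the same deposited FPKM, so a failed estimate can stay at 0 in it. Cct2 and Brd2 were at 0 in CD4SP in both values, and Gpbp1 and Rnf146 in CD8SP. Polg2 and Sox4 did not, and Senp3 went the opposite way, at 7.39 in CD4SP and 60.5 in CD8SP. The exon-based values of most of these CD8SP genes were above 0 in CD4SP, as for Kcna3 at 9.15 against 19.7. Cct2, a subunit of the chaperonin all cells use, is among the genes at 0, so a 0 here can be a failed estimate.

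Among genes above 0 in both libraries that also held in the exon-based value, a rule chosen after the data were seen, the largest ratios were as follows. In CD4SP, besides Zbtb7b, Cd4, Klra9, Chl1 and Cd40lg, these were St8sia6 (35.9-fold), Chdh (30.9-fold), Nav2 (20.7-fold), Eif4a1 (12.8-fold), H1f0, Tspoap1 and Myo10. In CD8SP, besides Itgae, Cd8a and Cd8b1, they were H4c12, the lysolipid receptor gene Gpr55 (54.1-fold), Plac8 (33.8-fold), Lcn4 (36.6-fold), the adhesion receptor gene Adgrg5 (27.3-fold), Ddc (30.2-fold), Elob, Ggt1 and Tmem108. The exon-based differences of some were far smaller, at 93.8 against 33.6 for Eif4a1, 68.4 against 192 for H4c12 and 0.707 against 2.86 for Tmem108. H4c12 is 1 of many near-identical histone genes.

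The 2 lineages mostly used the same annotated splice forms. Of 2984 events in which both forms are annotated in RefSeq, 516 (17.3%) differed by at least 20 points, 295 with higher PSI in CD8SP and 221 in CD4SP, in 400 genes. PSI correlated at 0.873 across these events, and 62.5% lay within 10 points. By type, 162 of 1006 skipped exons, 106 of 462 alternative 5' splice sites, 87 of 531 alternative 3' splice sites, 61 of 319 retained introns, 2 of 32 mutually exclusive exons, 91 of 574 alternative first exons and 7 of 60 alternative last exons were called. Restriction to annotated forms was chosen after the data were seen.

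Several annotated cassette exons differed in inclusion by at least 20 points. An exon of 36 bases of Synrg, a trafficking adaptor gene (chromosome 11, 84039656 to 84039691, coding), was included at 21.99% in CD4SP and 73.8% in CD8SP. Exon 15 of Ablim1, an actin-binding protein gene (chromosome 19, 57059085 to 57059204), was included at 54.7% and 17.2%, and exon 10 of the seryl-tRNA synthetase gene Sars (chromosome 3, 108427861 to 108427932) at 40.2% and 2.95%. An untranslated exon of the interferon-inducible gene Ifi213 was included at 7.24% and 53.4%, and exon 4 of Fam172a at 9.21% and 46.1%.

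Other annotated events involved introns, splice sites and terminal exons. A retained intron of Actr3, an actin nucleation gene, was at 33.9% in CD4SP and 67.0% in CD8SP, that of Men1 at 24.4% and 69.7%, and that of Ube2h at 100% and 47.7%. An alternative 5' splice site of the splicing factor gene Srsf5 (chromosome 12, 80945673 to 80945798, untranslated) was used at 45.2% and 87.2%. That value compares the site at 80945798 only with a site at 80945672. Against a shorter form (80945669 to 80945798), the site at 80945798 was used at 34.4% and 33.5%. Against the same shorter form (80945669 to 80945672), the site at 80945672 was used at 38.9% and 6.85%. The difference thus lay in lower use of the site at 80945672 in CD8SP, while the longest form against the shortest was similar. An alternative 5' splice site of the phosphatase gene Acp5 was used at 29.1% and 84.6%. An alternative 3' splice site of Npm1 was used at 0% and 81.1%. First exons of the phosphodiesterase gene Pde4b (100% and 47.5%) and of Sema4a (48.0% and 92.6%) also differed. The values of 0% and 100% for Ube2h, Npm1 and Pde4b mean that a form is at 0 FPKM in CD4SP, which can be a failed estimate.

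Annotated events of genes with T cell splicing already known mostly had similar PSI in both lineages, whereas over all their events 327 of 1086 were called. Of the 63 annotated events in 28 of these genes, 5 were called, with a median difference of 3.91 points. An exon of 72 coding bases of Ptprc, the CD45 phosphatase (chromosome 1, 138116954 to 138117025), was included at 78.4% in CD4SP and 79.5% in CD8SP. It is exon 4 of 30 in the GENCODE transcript Ptprc-203. Over all events of Ptprc, 7 were called, with a largest difference of 63.9 points, and 4 of them had both forms in both files. Exon 4 of Cd8a (chromosome 6, 71375888 to 71375918, 31 coding bases) was included at 60.1% and 63.7%, and exon 6 of Lef1 at 95.9% and 96.5%. Exon 5 of the lymphoid factor gene Ikzf1 (58.3% and 73.8%) and exon 6 of Ets1 (79.4% and 89.8%) differed by less than 20 points. So did a Cd6 exon of 117 bases, exon 5 of the GENCODE transcript Cd6-201 (93.8% and 79.7%). The 5 called annotated events were 3 choices of first exon of the chromatin organiser gene Satb1, a retained intron of Vav1 (77.0% and 97.47%) and exon 18 of Camk2d (57.8% and 37.7%).

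The Satb1 choices compared first exons ending at chromosome 17 positions 51826434, 51833163 and 51811768. A first exon at 51832470 carried most of the FPKM and differed little, at 81.8% and 83.8% against that at 51826434. The form with the exon at 51826434 rather than 51811768 made up 100% in CD4SP and 77.0% in CD8SP. The form at 51833163 rather than 51826434 made up 4.57% and 28.0%. The form at 51833163 rather than 51811768 made up 100% and 56.5%, on a summed FPKM of only 2.74 in CD4SP. The values of 100% mean that the form at 51811768 is at 0 FPKM in CD4SP, which can be a failed estimate. The choice between 51833163 and 51826434 does not rest on that form. In long reads Satb1 had 15 isoforms in CD4SP, of which 8 were multi-exon, and 8 in CD8SP, of which 2 were multi-exon.

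**Figure D3:**
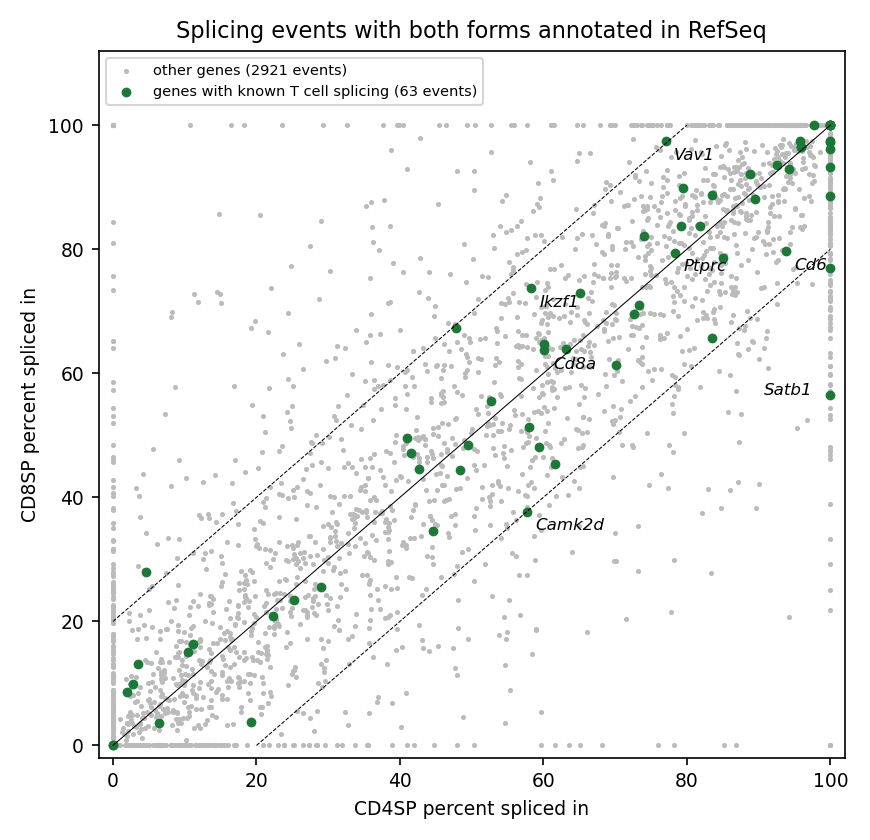
PSI in CD8SP against CD4SP for 2984 events whose forms are both in RefSeq, with 63 events of genes with known T cell splicing in green, the line of equality and dashed lines at a difference of 20 points. Events of Ptprc and Cd8a lie near the line, and a Satb1 first exon lies at 100% in CD4SP and 56.5% in CD8SP. Its 100% means that the other form is at 0 FPKM in CD4SP, which can be a failed estimate.

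Over all events, including forms assembled in a single library, more differed. Of 88240 events, 18241 (20.7%) were called in 4771 genes, 8277 higher in CD8SP and 9964 in CD4SP, and 2252 of them differed by 100 points. Of 94434 assembled intron chains, 4293 were found in both files. The fixed rule took 28 events, among them skipped exons of Sfpq, Chd3 and Nfs1, retained introns of Gramd1a, Srsf5, Satb1 and Rbm39, splice sites of Stk17b, Eif4a2, Lat, Serbp1 and Hnrnph1, mutually exclusive exons of Mndal, Oga and Eif4g2, first exons of Ikzf1 and Mbnl1, and last exons of Ets1, Skap1, Inpp4b and Fam172a. Of these, 27 differed by 100 points and 0 had both forms in both files. With both forms in both files, 3889 of 28365 events (13.7%) were called. Genes with known T cell splicing held their 327 called events in 47 genes, led by Satb1 with 47, Ikzf1 with 24, Clk4 with 20 and Tia1 with 19.

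Splicing regulators were expressed at similar levels. Among 56 measured, 1 was called higher in CD4SP and 1, Hnrnpab, in CD8SP (75.9 against 185 FPKM). The call of Hnrnpab did not hold in the exon-based value (75.9 against 107). The median log2 ratio was 0.13 at percentile 4.17, or -0.08 after scaling. After scaling Srsf10 and Thrap3 were also called in CD4SP, but not borne out by their unscaled exon-based values. These were 14.6 in CD4SP and 18.3 in CD8SP for Srsf10, and 14.7 and 14.6 for Thrap3. Of 63 genes with known T cell splicing, 5 were higher in CD8SP and 7 in CD4SP, with a median of -0.26 at percentile 0, and the largest ratios were those of Zbtb7b, Cd4, Cd8a and Cd8b1, which are also lineage genes. Of 74 annotated events in splicing regulators, 6 were called, in Hnrnpa3, Celf2, Srsf5, Srsf7 and Ddx17, and over all their events 469 of 1322 were called, in 51 genes. The event of Hnrnpa3 rests on assembled transcripts that share introns with another gene too and are left out of its gene FPKM, which is listed at 0 in both libraries.

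Long reads placed most isoforms outside full annotated structures in both lineages. Full splice matches made up 7.87% of CD4SP and 8.42% of CD8SP isoforms. Incomplete matches were fewer in CD4SP, at 17.3% (95% interval 16.5 to 18.2) against 20.8% (19.98 to 21.6), with an adjusted p of 4.41e-08 by the 2-sided Fisher's exact test. Isoforms classed as 5' fragments made up 51.0% of the incomplete matches in CD4SP and 56.0% in CD8SP (exact test, adjusted p = 0.0142). The median isoform length was 2882 bases in CD4SP and 2597 in CD8SP, so incomplete transcripts may have part in this difference, which was not tested. Antisense isoforms were more frequent in CD4SP, at 26.2% against 23.2% (exact test, adjusted p = 1.29e-05), and intergenic ones less frequent, at 3.84% against 4.69% (exact test, adjusted p = 0.0125). The other 4 categories did not pass. Among multi-exon isoforms alone, intergenic ones did not differ past the threshold, at 0.689% and 0.597% (exact test, adjusted p = 0.747), while those with an unannotated splice site did, at 20.1% and 17.7% (exact test, adjusted p = 0.0297). Without isoforms with A-rich 3' ends, a restriction chosen after the data were seen, only incomplete matches differed, at 39.7% in CD4SP and 44.5% in CD8SP (exact test, adjusted p = 0.000416). Among isoforms of annotated genes, 64.0% in CD4SP and 59.5% in CD8SP had an unannotated structure (exact test, p = 2.77e-07), and among multi-exon ones 42.8% and 38.2%. This share is what full and incomplete matches leave, so it is not a result separate from theirs. Each test compares 2 libraries and not the lineages.

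**Figure D4:**
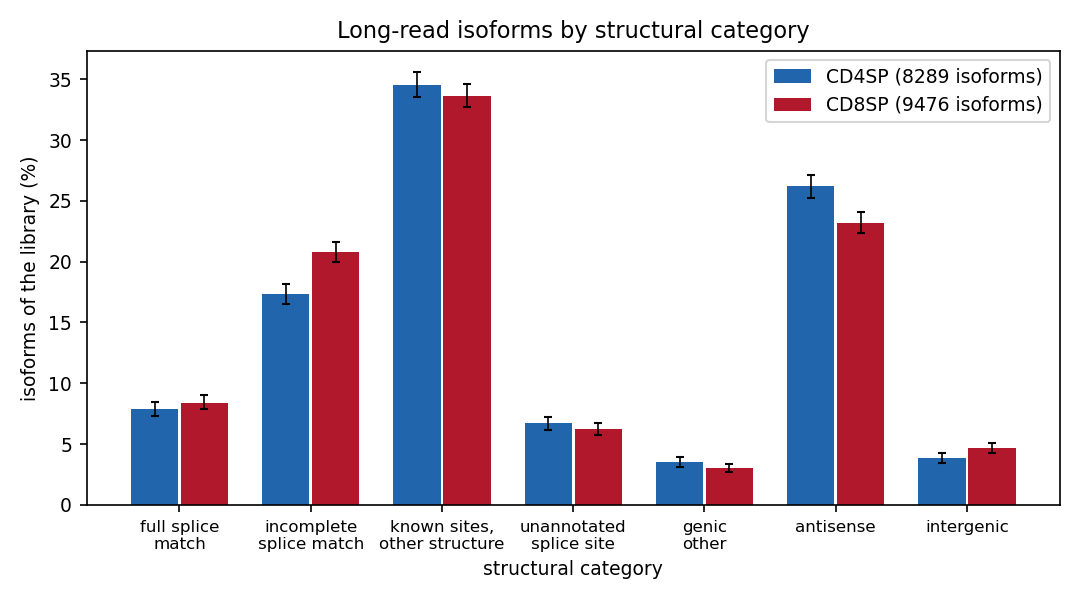
Percent of long-read isoforms in each structural category for CD4SP (8289 isoforms) and CD8SP (9476 isoforms), with exact 95% intervals for counting error. Incomplete splice matches stand at 17.3% and 20.8% and antisense isoforms at 26.2% and 23.2%.

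Single-exon isoforms made up 66.8% of the CD4SP and 64.7% of the CD8SP catalogue. Their genomic 3' ends were mostly A-rich, at 83.8% in CD4SP and 81.1% in CD8SP. Multi-exon full matches were A-rich in 9.32% and 11.2%, and antisense single-exon isoforms in 96.6% and 96.0%.

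**Figure D5:**
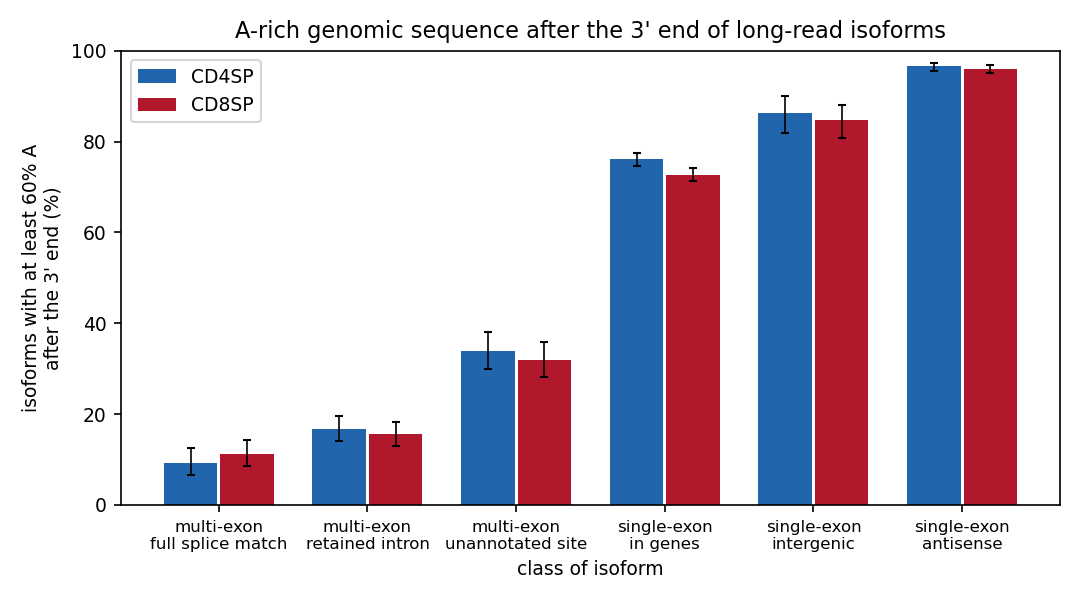
Percent of isoforms with at least 60% A after their 3' end, by class and library, with exact 95% intervals. Multi-exon full matches lie at 9.32% in CD4SP and 11.2% in CD8SP, and antisense single-exon isoforms at 96.6% and 96.0%.

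The libraries shared part of their genes and reference transcripts. Isoforms of any kind were found for 2295 genes in both libraries, and multi-exon isoforms for 876 genes, out of 1318 in CD4SP and 1703 in CD8SP. Multi-exon full matches covered 345 reference transcripts in CD4SP and 462 in CD8SP, of which 197 were common. The guanine exchange factor gene Arhgef1 had the most isoforms, 43 in CD4SP and 44 in CD8SP, of which 37 and 34 retained an intron. Ppp2r5c had 33 and 25, AC149090.1 had 24 and 24, Gm26551 had 24 and 16, and the class I gene H2-K1 had 14 and 22. Runx3 had 1 isoform in CD4SP and 7 in CD8SP, and Itgae 0 and 5. Numbers of isoforms depend on depth, which is unknown.

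Shares of isoforms of the chained long-read catalogue were mostly similar in both lineages. These TPM values were taken to come from the short reads, which no source used here states. Of 1308 loci tested, 118 (9.02%) held an isoform whose share differed by at least 20 points. The leading isoform differed in 120 loci. The median difference over the 4650 isoforms of these loci was 1.08 points, which minor isoforms with shares near 0 in both lineages lower. In locus PB.1629, isoform PB.1629.3 made up 100% in CD4SP and 0% in CD8SP, where PB.1629.1 took its place, and PB.3075.1 and PB.3075.2 exchanged places in the same way. A single isoform took 32.5% of all TPM in CD4SP and 27.2% in CD8SP, so the TPM of the others is relative to it.

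Long and short reads ranked genes alike only weakly. Across 3615 genes, the log2 ratio of isoform numbers and that of FPKM correlated at a Pearson coefficient of 0.160 and a Spearman coefficient of 0.171. Of 295 called genes with unequal isoform numbers, 216 (73.2%) had more isoforms in the lineage with the higher FPKM, where 56.5% would follow from the totals alone, since 211 of these genes were higher in CD8SP and 192 had more isoforms there. Among those higher in CD4SP it was 54 of 84. Isoform numbers are not expression levels, and genes are not independent replicates.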

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

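The test of unspliced sense transcripts, the split of annotated and other events by level, and the split by forms in both files were chosen after their results were seen. The other tests of this part were set before. Signals outside the main comparisons were marks for reverse transcriptase switching on 357 CD4SP and 402 CD8SP long-read isoforms, and 584183 CD4SP and 540449 CD8SP short-read transcripts listed without a strand.

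Single-exon isoforms made up most of both long-read catalogues. Unspliced sense transcripts of annotated genes are argued against as the whole cause, because 39.4% of single-exon isoforms in CD8SP and 40.5% in CD4SP were classed antisense or intergenic. Internal priming on A-rich genomic stretches may account for many of them, since A-rich 3' ends exceeded those of multi-exon full matches by 69.9 points in CD8SP and 74.5 points in CD4SP. The pattern is present in both lineages, and no further explanation was tested.

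Splicing events differed between the short-read libraries. Low coverage may account for part of the calls, as the call rate at a summed FPKM of 20 or more was 0.160 of that below 5, at 5.49% against 34.2%. Isoforms assembled in a single library stay open, because the call rate of events with both forms in RefSeq was 0.832 of that of other events, between the bounds set for either outcome, and the rates were 25.0% against 34.6% below 5 FPKM, 10.4% against 9.98% from 5 to 20 and 8.60% against 5.37% at 20 or more. Events with both forms in both files were called at 13.7%, and held only 22 of the 2252 differences of 100 points. Most of these largest differences thus had a form missing from a file, and a missed form cannot be told apart from an absent one. A difference between the lineages stays open too, since no replicate separates lineage from library.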

How the results depend on the processing

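Alternatives with RefSeq forms, forms in both files, A-rich ends, single-exon isoforms among shared transcripts, exon-based values, genes above 0, and the TPM and share thresholds were chosen after the data were seen. Scaling changed the sign of 1 list median, that of splicing regulators, which lay within the range of random lists, and 18 of 33 alternatives of the main results stayed within 1.5 times or on the same side of the test. The 1422 called genes became 881 with a pseudocount of 1, 699 and 2317 with an FPKM minimum of 5 and none, and 3116 and 430 with log2 ratios of 0.58 and 2. The 18241 called events became 4361 at an FPKM minimum of 5, 38430 and 10913 at 10 and 30 points, 516 with RefSeq forms, where most were higher in CD8SP rather than in CD4SP, and 3889 with both forms in both files. With multi-exon isoforms alone 3 structural categories again differed: incomplete matches and antisense isoforms as before, and isoforms with an unannotated splice site in place of intergenic ones. Without A-rich ends, 1 structural category differed in place of 3. Shared reference transcripts numbered 323 with single-exon isoforms. The 118 loci with different usage became 59 at 10 TPM, and 282 and 70 at 10 and 30 points. These settings loosen or tighten a threshold or change what is counted, and beyond that the cause was not tested. Not run, for lack of full-length read counts, exon positions or matched identifiers, were read minimums, weighting and thinning by reads, exact or 5-base matching of intron chains, the chained identifiers, and tests of usage on reads. No paired analysis was possible because the lanes of each lineage are pooled in 1 file. Depth is unknown, so absence from a catalogue is not absence from the cells.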

Other observations

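For the CD8SP-cell test, the reading of genes at 0 was decided after the result was seen, and the other test of this part was set before. Isoforms with a retained intron were more frequent in CD4SP in long reads. Among all called short-read retained introns, more had higher PSI in CD4SP, but not among annotated forms. Among multi-exon long-read isoforms in genes, 28.9% in CD4SP and 25.4% in CD8SP retained an intron (Fisher's exact test, adjusted p = 0.0142), and 20.1% and 17.2% of coding ones were predicted to undergo nonsense-mediated decay (exact test, adjusted p = 0.0349). Of called retained introns in short reads, 5518 had higher PSI in CD4SP and 3876 in CD8SP, and 1222 and 874 where both forms were in both files. Among RefSeq forms the split was 29 in CD4SP and 32 in CD8SP. These short-read numbers count events and not isoforms, and 1 transcript can enter several events. The CD4SP file also held more assembled intron chains, 51129 against 47598. Among single genes, Ptpn6 had 1 long-read isoform with a retained intron in CD4SP and 3 in CD8SP, Clk1 3 and 1, and Hnrnpl 9 and 12, chosen after their values were seen.

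Cd8a and Cd8b1 transcripts were present in the CD4SP library at 4.52% and 6.53% of their CD8SP levels, although the sort excluded CD8-positive cells. CD8SP cells in the CD4SP sort were tested on 23 genes at 20 FPKM or more and at least 8-fold higher in CD8SP, and 6 of them had an upper CD4SP bound below 0.5 of the Cd8a ratio, where 3 had been set beforehand as enough to exclude this explanation. That bound is held to be wrong here, because all 6 (Cct2, Brd2, Mir1929, Snora64, Snord15a and Snora3) are listed at 0 in CD4SP, where Cct2 and Brd2 show that a 0 can be a failed estimate, and 0 of the genes above 0 met it. Itgae (1.66%, upper bound 2.66%) lies below Cd8a and Nkg7 (7.23%) and Xcl1 (12.1%) above it, so CD8SP cells may contribute and no share can be given. Double-positive thymocytes, which bead depletion and the gate would remove, cannot be told apart from low transcription in CD4SP cells, since 3 of 10 immature thymocyte genes were higher in CD4SP with separate intervals, between the bounds set for either outcome.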
